A study of Mus musculus with 8 samples.

How the data were processed

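Single-cell expression and B cell receptor libraries were made from live immune cells of deep cervical lymph nodes, sorted by FACS, with the 10x Genomics 5' V2 chemistry, per the labels' protocols. There were 5 expression libraries and 3 receptor libraries, 1 per group. The number of mice behind a library, and whether the saline control mice were given isotype antibody, are not given in the sources used here. The deposited expression tables hold counts, UMIs per gene and barcode for 32285 genes, made with Cell Ranger 7.0.1, per the file headers, after bcl2fastq 2.20.0 and on genome build mm10, per the submitters' processing notes. The deposited receptor tables hold, per assembled contig, counts of UMIs and reads and the names of the V, J and constant genes with the nucleotide sequence of each region, per the file headers, and every contig listed is productive and of full length. The annotation release and the settings of cell calling are not given in the sources used here. Gene symbols and IDs were taken from the deposited tables, and coordinates of 251 of 252 genes looked up from the mm10 annotation at hand.

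The tables held 9846, 9641, 11791, 9014 and 9107 barcodes in the saline control, isotype, anti-CTLA-4, depleted isotype and depleted anti-CTLA-4 libraries. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were used. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked 3.23%, 3.58% and 4.41% of barcodes in the first 3 libraries and none in the depleted ones, so the barcodes with the highest scores were removed instead, 0.8% per 1000 barcodes, which took 776, 744, 1112, 650 and 663 barcodes. The kept cells had medians of 4679, 4574, 4261.5, 5885.5 and 6026 UMIs. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen without immunoglobulin and T cell receptor segments, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave the clusters (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). All cells were clustered together, and B cells, T cells, CD4 T cells and antigen-experienced CD4 T cells were each clustered again. Clusters were named from 23 marker sets. The marker sets of the germinal centre B-like and Tfh-like classes hold the same genes as the germinal centre and Tfh programme lists. A cluster counted as B lineage or T cells with at least 5 UMIs per 10000 of Cd79a plus Cd79b or of Cd3e plus Cd3d, as CD4 or CD8 at a ratio of 3 between them, as Treg-like with at least 1 UMI per 10000 of Foxp3, as effector at a score of 0.5, and as Tfh-like at a score of 0.6 that was also at least 0.75 times the highest. The last threshold and the naming thresholds were set after the clusters were seen. Other classes needed at least 3 markers, each with UMIs in at least 5% of cells. No class compared had a cluster with more markers of another class among its 10 leading genes.

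Shares of cells were given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of shares with 95% log intervals. UMIs of each gene were summed per library and class, given as CPM (counts scaled to a common total per class) with exact Poisson intervals, and compared as ratios with exact conditional binomial intervals. This was done in follicular B-like, germinal centre B-like, conventional CD4 T, Treg-like and CD8 T-like cells, where both libraries held at least 50 cells of the class. Other classes were not compared this way, whatever their number of cells. A group at 0 was set to a floor of 3 counts over the class and its ratio written as a bound. Of the 17 gene lists, members with at least 20 UMIs over both libraries entered the median log2 ratio, which was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. The lists were the germinal centre programme, IgG constant genes, other immunoglobulin constant genes, antibody secretion and ER folding, MHC class II presentation, B cell activation, type I interferon response, interferon gamma response, immediate early and heat shock, Tfh programme, Treg programme, T cell activation and checkpoints, cytotoxic effector, naive T cell quiescence, cell cycle, glycolysis and oxidative phosphorylation. The 5 comparisons were isotype glioma over saline control, anti-CTLA-4 over isotype with B cells, depleted over not depleted under isotype and under anti-CTLA-4, and anti-CTLA-4 over isotype after depletion. With 1 library per group no p-value was computed.

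The genes named were chosen by a rule. In each comparison and class it took the 3 genes with the highest and the 3 with the lowest ratio, ranked by the interval bound nearest 1, among genes with at least 100 UMIs. Immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes, unnamed gene models and genes under 10 percent of their highest class level in the same library, as possible free RNA, were left out of the ranking. The members with most UMIs of each list, the immunoglobulin constant genes, Ms4a1 and Ctla4 were named as well. Any other gene is said to be chosen after its values were seen. The rule, the lists, the marker sets, the comparisons and the first set of alternatives were set before the data were examined.

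In the receptor tables the heavy chain with most UMIs stood for a barcode. A clone was a set of cells with the same V gene, J gene and CDR3 nucleotide sequence, and the number of distinct clones was taken at 4496 cells per library over 1000 subsamples. Mutation was counted as mismatches of the V segment against the most common sequence of the same V gene and length among IgM and IgD cells of the 3 libraries, with at least 20 such cells per reference. There were 77 references, which covered 14246 of 14380 cells, and a cell with at least 2 mismatches was called mutated. Barcodes were matched to the expression library of the same treatment label, and 87.8%, 87.3% and 84.8% of cells with a heavy chain were kept B lineage cells in the saline control, isotype and anti-CTLA-4 libraries.

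The gene levels and list medians were tested on simulated data drawn from the anti-CTLA-4 comparison with 200 genes changed by known factors. Each gene was drawn independently as Poisson counts, the setting that the intervals assume. The simulation therefore checks the code only. It holds no UMIs piled up in single cells, no genes that vary together and no spread between mice. At a depth scale of 0.2, with 12608 genes, 95.7% of the intervals of unchanged genes held the true ratio, 2% of unchanged lists fell outside the central 95%, and the medians of doubled and halved genes came out at 1.97 and 0.483. At a scale of 0.02, with 8560 genes, these were 96.7%, 5.5%, 2.03 and 0.480.

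The alternatives tried were no doublet removal, at least 200 genes with at most 20% mitochondrial UMIs, Leiden resolution 2, variable genes with receptor segments, marker gates of at least 3 genes (1 gene, Foxp3, for Treg-like cells) on cells thinned to 1000 UMIs, median-ratio size factors, totals without receptor, mitochondrial and ribosomal genes, list members with at least 100 UMIs, and for the receptors only B lineage barcodes, exactly 1 heavy and 1 light chain, at least 3 UMIs, clones at 85% CDR3 identity, with the light chain or from the authors' software, at least 5 mismatches and references from the other libraries. Added after the data were seen were leaving out cells under 0.5% mitochondrial UMIs, leaving out the cell with most UMIs of a gene, leaving Tfh-like cells (but not the kept-out cluster) out of the conventional CD4 T cells, leaving out B cells with a UMI of Cd3d, Cd3e, Cd3g or Ctla4 (which takes more of the deep cells), counting the kept-out cluster as Tfh-like, and giving mutated shares by antibody class. The shares of the antibody classes themselves were set before the data were examined. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and anndata 0.12.19, with figures drawn in matplotlib 3.10.9. Light chain mutation and T cell receptor segments were not analysed here.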

Results

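Single-cell gene expression was measured in deep cervical lymph nodes of C57BL/6 mice 20 days after GL261 cells, a mouse glioma line, or DPBS, the saline control, had been injected into the brain. The 5 expression libraries were a saline control library, an isotype library and an anti-CTLA-4 library from glioma-bearing mice with B cells, and an isotype and an anti-CTLA-4 library from glioma-bearing mice treated with anti-CD20, which removes B cells. The saline control, isotype and anti-CTLA-4 mice with B cells also gave 3 B cell receptor libraries. Each group had 1 library, so no value has a replicate check and no difference was tested. In the order above the expression libraries held 54715065, 55770528, 63497466, 61019425 and 62150813 UMIs, and 9027, 8845, 10598, 8302 and 8363 cells were kept. The receptor libraries gave a heavy chain for 4496 cells of the saline control, 4522 of the isotype and 5362 of the anti-CTLA-4 library. All cells were live immune cells sorted by FACS, so shares of cells are shares of that sort, and all intervals are 95% intervals that cover counting error only. Cell classes are named after the markers of their clusters, and a list of genes is called higher or lower where its median log2 ratio fell outside the central 95% of 10000 random lists of like expression. Of 301 list medians 49 lay above and 63 below that range, which leaves out 5% of random lists. Genes of random lists were drawn independently, while genes of a named list may vary together, and comparisons share libraries. The 5% is therefore not the rate to be met without a treatment effect.

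The targets of both antibodies came first, as a check of the labels. Ms4a1 (ENSMUSG00000024673, chromosome 19, 11249679 to 11266149, mm10) encodes CD20 and stood at 275 CPM (UMIs scaled to a common total) in the saline control, 246 in the isotype and 282 in the anti-CTLA-4 library. After anti-CD20 it stood at 8.02 CPM in the isotype library and 10.2 in the anti-CTLA-4 library, 0.0326 (0.0296 to 0.0359) and 0.0360 (0.0331 to 0.0392) times the libraries with B cells. Ctla4 (ENSMUSG00000026011, chromosome 1, 60909025 to 60915832) stood at 68.3 CPM in the saline control, 75.3 in the isotype, 88.03 in the anti-CTLA-4, 128 in the depleted isotype and 139 in the depleted anti-CTLA-4 library. An antibody that blocks CTLA-4 protein need not change its RNA, so Ctla4 checks no label. Within Treg-like cells, the class with most Ctla4, anti-CTLA-4 gave 0.929 (0.877 to 0.985) times the isotype level.

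The first comparison asked how the draining nodes of glioma-bearing mice differed from those of saline-injected mice. The isotype glioma library held more antibody-secreting and germinal centre B-like cells and more class-switched IgG receptors than the saline control, while the shares of Treg-like and Tfh-like cells could not be told apart at this depth. Interferon-induced genes were lower in follicular B-like cells of the glioma library. Plasma cell-like cells made up 0.0665% of all cells in the saline control (6 cells) and 0.452% in the glioma library (40 cells), a ratio of 6.80 (2.89 to 16.0). Of 36 such glioma cells with a receptor 24 were in clones, and 10 were in 1 clone. The interval counts each cell as independent and may be too narrow. Germinal centre B-like cells made up 0.561% (0.363 to 0.827) of B lineage cells in the saline control and 1.43% (1.11 to 1.82) in the glioma library, a ratio of 2.55 (1.61 to 4.04) that a gate on 3 marker genes lowered to 1.16. Tfh-like cells, the helpers of germinal centres, made up 0.502% and 0.786% of CD4 T cells, a ratio of 1.56 (0.720 to 3.40) whose interval holds 1 and whose direction turned in other settings, to 0.901 with a further cluster counted as Tfh-like and 0.545 with no doublet removal. Treg-like cells made up 19.2% and 20.4% of CD4 T cells.

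**Figure D1:**
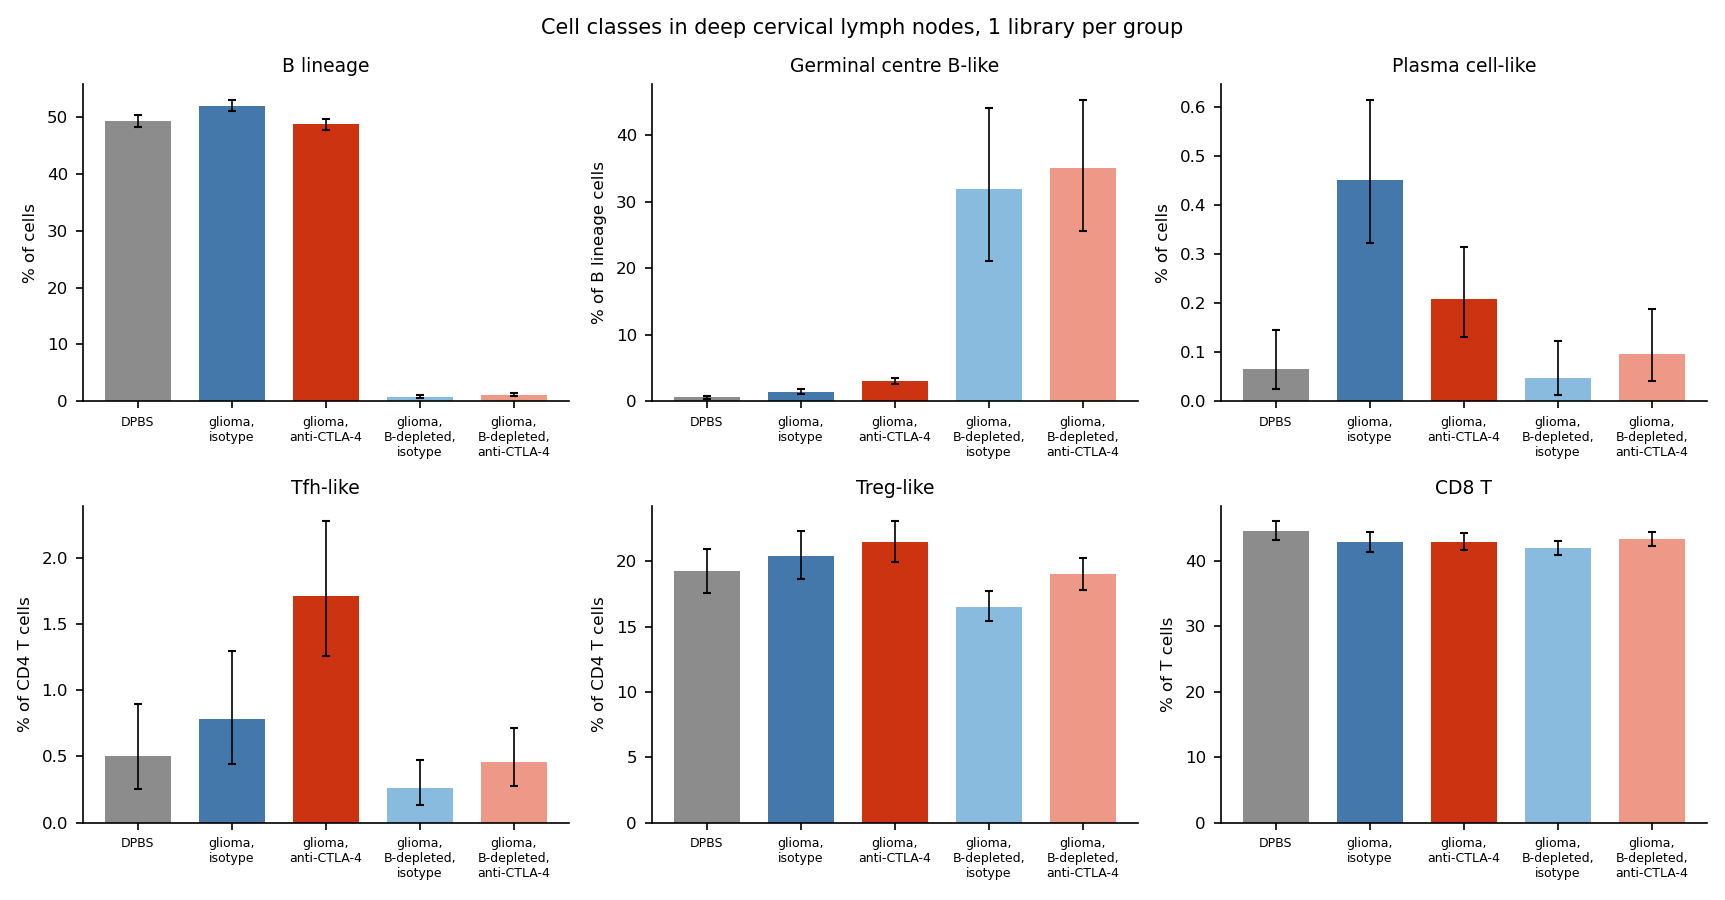
Shares of cells (percent, y axis) of 6 classes in the 5 expression libraries, with bars for the share and lines for its exact 95% binomial interval. The B lineage made up 49.4%, 52.1% and 48.8% of the libraries with B cells and 0.831% and 1.16% of the depleted ones.

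In follicular B-like cells the IgG constant genes had a median log2 ratio of 2.14, glioma over saline control, with all 4 members higher. Ighg2b was 5.63 (3.69 to 8.90) times and Ighg1 3.58 (1.95 to 7.00) times the saline level (6.17 without the top cells), and Ighg2c was at least 13.1-fold higher, with 40 UMIs against 0. These genes lay under 1% of their plasma cell-like level, as free RNA would, while Ighm (1.01) and Ighd (1.06), which encode the unswitched receptor, were level. Type I interferon response genes had a median of -0.39, with 13 of 15 lower, or -0.23 among members with at least 100 UMIs. Of its members with many UMIs Ifi27l2a was at 0.954 and Bst2 at 1.003, and Ifit3, which blocks viral RNA, was at 0.249 (0.187 to 0.328). Cell cycle genes were higher with a median of 0.97 (Pcna 1.18, Mcm6 1.10, Mcm4 1.12), a value of 0.40 among members with at least 100 UMIs and 0.60 without B cells that held a UMI of a T cell gene. Socs3, an inhibitor of cytokine signalling, was at 3.24 (2.88 to 3.65), the chaperone Hspb1 at 2.52 (2.27 to 2.81) and Osgin1, an oxidative stress gene, at 3.30 (2.22 to 5.03). Immediate early and heat shock genes had a median of 0.13 (Junb 1.10, Jund 1.02, Hspa1b 2.04). The glioma library had the lowest median share of mitochondrial UMIs (1.01% against 1.77% to 2.09% in the other libraries), and Socs3 led a follicular B-like cluster with 195 of its 197 cells from it. Hspa1a and Hspa1b led another follicular B-like cluster and a CD4 T cluster.

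In Treg-like cells the type I interferon list had a median of -0.35 (Isg15 0.546, Bst2 0.851, although Ifi27l2a was at 1.09), or -0.23 and inside the range of random lists among members with at least 100 UMIs, and the Tfh list of -0.25, with all 10 members lower (Izumo1r 0.836, Icos 0.895). Pdcd1, the gene of the checkpoint receptor PD-1, was at 0.470 (0.368 to 0.598) there, and Socs3 at 2.47 (2.09 to 2.92). Genes of naive T cell quiescence had a median of 0.15 in Treg-like cells (Ccr7 1.11, Klf2 1.39, Satb1 1.29), and oxidative phosphorylation genes one of 0.12, or 0.18 with median-ratio size factors. CD8 T-like cells had the opposite direction in the type I interferon list, with a median of 0.16 and 12 of 15 members higher (Irf7 1.12, Ifi27l2a 1.11), and the cold shock gene Cirbp was at 1.67 (1.53 to 1.82) and Map3k8, a kinase of cytokine signalling, at 1.89. The chaperone partners Stip1 (0.654) and Chordc1 (0.641) were lower in CD8 T-like cells. Among CD4 T cells outside the Treg-like clusters, here called conventional and holding the Tfh-like cells, the opioid precursor Penk was at 13.2 (9.71 to 18.4), with UMIs in 11 against 12 cells, and Sostdc1, a gene that leads the Tfh-like cluster, at 11.1 (6.83 to 19.2), in 9 against 3 cells. The Tfh programme of this class had a median of 0.21, or -0.092 without the Tfh-like cells. Il17a was at least 45.6-fold higher in them, but 1 cell held all its 119 UMIs. Spp1 was at 0.0559, but 1 saline control cell held 98% of its UMIs and without it the ratio was 1.15.

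The second comparison asked how anti-CTLA-4 differed from isotype in glioma-bearing mice with B cells. Germinal centre B-like cells and Tfh-like cells held larger shares under anti-CTLA-4, the germinal centre programme was higher within germinal centre B-like cells, and their receptors were IgG1 more often. Conventional CD4 T cells, a class that holds the Tfh-like cells, carried more RNA of the Tfh programme and of activation and checkpoint genes. The medians were smaller once those cells were left out, with a further cluster of high Tfh score still counted. Tfh-like cells were named on the genes of the Tfh programme. Leaving them out therefore draws that median towards no change, whatever happened within the other cells. Germinal centre B-like cells made up 3.03% (2.58 to 3.54) of B lineage cells against 1.43%, a ratio of 2.12 (1.59 to 2.82), or 5.28 with the gate on 3 marker genes. The gate counts genes of the germinal centre programme, which were higher within the class under anti-CTLA-4. Its ratio therefore mixes the number of cells with the level per cell. Tfh-like cells made up 0.786% (0.440 to 1.29) of CD4 T cells under isotype and 1.71% (1.26 to 2.28) under anti-CTLA-4, a ratio of 2.18 (1.22 to 3.89), which was 5.25 with no doublet removal and 1.27 at Leiden resolution 2. Il4, Sostdc1 and Asb2 led this cluster, so their levels in CD4 T cells move with its cells. A cluster kept out of the Tfh-like class by a score threshold set after the data were seen held 0.776% of CD4 T cells in the saline control, 0.367% in the isotype, 1.04% in the anti-CTLA-4, 0.694% in the depleted isotype and 0.557% in the depleted anti-CTLA-4 library. Plasma cell-like cells made up 0.208% of all cells, 0.459 (0.273 to 0.772) times the isotype share, and Treg-like cells 21.5% of CD4 T cells. Among plasma cell-like cells with a receptor 24 of 36 under isotype and 11 of 21 under anti-CTLA-4 were in clones. The interval of their ratio may therefore be too narrow. Clusters of mixed T cells, not named as CD4 or CD8, held 4.34% of T cells in the saline control, 8.49% in the isotype, 4.48% in the anti-CTLA-4, 4.72% in the depleted isotype and 4.40% in the depleted anti-CTLA-4 library, and 1 of them, led by Camk1d, had 221 of its 222 cells from the isotype library.

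Within germinal centre B-like cells (157 under anti-CTLA-4, 66 under isotype) all 11 genes of the germinal centre programme were higher, with a median log2 ratio of 0.63. The class may hold different mixtures in these libraries, since the gate on 3 marker genes took 71 and 12 B lineage cells, and Ctla4, a T cell gene chosen after its values were seen, was at 0.0809 (0.0332 to 0.171). A UMI of Cd3d, Cd3e, Cd3g or Ctla4 was held by 14 and 12 cells, with medians of 19395.5 and 28924 UMIs, and without these cells, a setting chosen after seeing the data, all 11 genes were still higher, with a median of 0.48. Basp1 was at 1.64, Mef2b at 1.13, Eaf2 at 1.30 and Rgs13, a brake on chemokine receptor signalling, at 2.74 (2.26 to 3.34). Bcl6, the master regulator, was at 1.31, or 1.11 (0.881 to 1.40) without cells with T cell genes, and S1pr2, which confines cells to the centre, at 1.91, both chosen after their values were seen. Interferon gamma response genes had a median of -0.74 (Psmb8 0.852, Psmb9 0.704, Tap1 0.585), and genes of antibody secretion and ER folding one of -0.18 (Herpud1 1.21, Hspa5 0.846, Hsp90b1 0.660), which turned to 0.18, inside the range of random lists, without cells with T cell genes. Cell cycle genes had a median of 0.18 (Stmn1 1.19, Pclaf 1.26). The IgG constant genes went both ways, with a median of -1.19. Ighg1 was at 4.29 (3.63 to 5.10), or 3.47 without the cell with most of its UMIs and 2.61 (2.12 to 3.26) without cells with T cell genes, while Ighg2b was at 0.0575 (0.0391 to 0.0820), Ighg2c at 0.406 and Ighg3 at 0.473. Ighm stayed at 0.983, Ighd was at 0.379, and Igha was at 24.7 with 86% of its UMIs in 1 cell, and at 2.65 without cells with T cell genes. Capg, an actin-capping gene, was at 0.383 (0.280 to 0.520), the membrane tether Esyt1 at 0.371 (0.245 to 0.557) and Hbb-bh1, an embryonic globin, at 0.275 (0.187 to 0.399). Trmt1l was at 2.94 (1.74 to 5.25) and Syne1, a nuclear envelope anchor, at 2.33 (1.70 to 3.26).

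The receptor libraries asked the same questions of antibody class, mutation and clones. Their intervals treat each cell as an independent draw, although cells of the same clone share a V gene, J gene and CDR3 sequence. Where clones are large the intervals may be too narrow. IgG1 was the constant gene of 0.111% (0.0361 to 0.259) of cells with a heavy chain in the saline control, 0.464% (0.288 to 0.709) in the isotype and 1.53% (1.22 to 1.89) in the anti-CTLA-4 library. The ratios were 4.18 (1.58 to 11.1) for glioma over saline and 3.29 (2.04 to 5.31) for anti-CTLA-4 over isotype. IgG2b was at 4.72 (1.61 to 13.9) and IgG2c at 3.58 (1.33 to 9.63) with glioma (IgG2b at 8.50 among B lineage barcodes alone), and neither was higher under anti-CTLA-4 (0.533, 0.259 to 1.10, and 0.609, 0.299 to 1.24). IgG1 thereby made up 26.3%, 35.0% and 75.2% of IgG cells in the 3 libraries. Of the 82 IgG1 cells under anti-CTLA-4, 60 were germinal centre B-like and 2 plasma cell-like, and they fell into 58 clones. Of the 21 under isotype, 7 were germinal centre B-like and 10 plasma cell-like. Among germinal centre B-like cells with a receptor, IgG1 cells were 1 of 16 in the saline control, 7 of 43 under isotype and 60 of 109 under anti-CTLA-4, with a ratio of 3.38 (1.68 to 6.80) for the latter pair. IgE was seen in 0 cells, which allows up to 0.0667%, 0.0663% and 0.0559%, taking 3 cells as the limit of a count of 0.

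**Figure D2:**
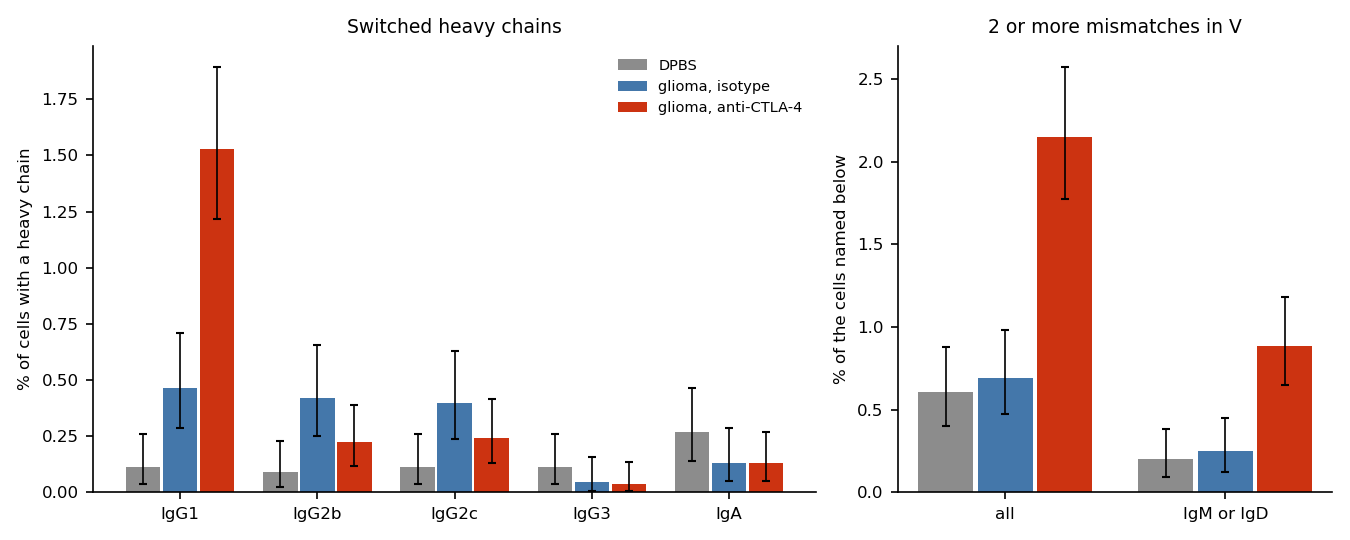
Shares of cells with a heavy chain (percent, y axis) by switched antibody class (left) and with at least 2 V segment mismatches (right, all cells and IgM or IgD cells) in the 3 receptor libraries, with bars for the share and lines for its exact 95% binomial interval. IgG1 stood at 0.111%, 0.464% and 1.53% in the saline control, isotype and anti-CTLA-4 libraries.

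V segments with at least 2 mismatches to the common sequence of the gene were found in 0.605%, 0.693% and 2.15% of cells of the saline control, isotype and anti-CTLA-4 libraries, a ratio of 3.10 (2.09 to 4.60) for anti-CTLA-4 over isotype. Among IgM and IgD cells that ratio was 3.54 (1.84 to 6.83), or 8.47 (1.08 to 66.1) with at least 5 mismatches, from 10 cells against 1. Within follicular B-like cells the anti-CTLA-4 ratio was 0.999 (0.363 to 2.75), from 8 mutated cells against 7. Germinal centre B-like cells held 70 mutated cells against 17, so the ratio for all cells also reflects the mix of classes. IgG cells were mutated in 84.2% of cases in the saline control (16 of 19), 29.3% with glioma and isotype (17 of 58) and 58.3% with anti-CTLA-4 (63 of 108). Their ratio was 0.348 (0.223 to 0.543) for glioma over saline, which at least 5 mismatches lowered to 0.140, and 1.99 (1.29 to 3.06) for anti-CTLA-4 over isotype. These IgG cells were a different mix in each library, with 1 of 19, 24 of 60 and 16 of 109 plasma cell-like. Among germinal centre B-like IgG cells 9 of 9, 11 of 18 and 42 of 63 were mutated, ratios of 0.611 (0.423 to 0.883) and 1.09 (0.726 to 1.64), the latter with an interval that holds 1. The log interval of the first ratio takes no counting error from a share of 9 of 9. It is therefore too narrow and does not set the saline control apart. Of these 9 saline control cells 3 were of 1 IgG3 clone. The ratio for all cells of glioma over saline was 1.15 (0.685 to 1.92), which turned to 0.449 with at least 5 mismatches. Clones of at least 2 cells held 1.96%, 1.92% and 1.44% of cells, and the ratio for anti-CTLA-4 was 0.746 (0.551 to 1.01), or 1.06 where clones were joined at 85% CDR3 identity and 0.604 (0.425 to 0.858) where the light chain had to match too. The anti-CTLA-4 ratio of the share in clones differed by class. In follicular B-like cells it was 0.302 (0.147 to 0.619), from 10 against 29 cells in clones. In germinal centre B-like cells it was 1.36 (0.770 to 2.41), from 38 against 11 cells, with an interval that holds 1. At 4496 cells per library the 3 libraries held 4448, 4442 and 4456 distinct clones.

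Conventional CD4 T cells under anti-CTLA-4 had a median log2 ratio of 0.37 in the Tfh programme, with 11 of 12 genes higher. The folate receptor Izumo1r was at 1.22, the signalling adaptor Sh2d1a at 1.38, Slamf6 at 1.24 and the costimulator Icos at 1.38. T cell activation and checkpoint genes had a median of 0.29 (Cd28 1.19, Tox 1.23, Cd69 1.22), and the Treg programme one of 0.36 (Ctla4 1.33, 1.19 to 1.48, Tnfrsf4 1.22, Ikzf2 1.66). Without the Tfh-like cells, a setting chosen after seeing the data, these medians were 0.28, 0.24 and 0.38. The kept-out cluster stayed in that setting, at 2.84 (1.24 to 6.49) times its isotype share of CD4 T cells (28 against 7 cells). These medians therefore do not separate a change within cells from a change in the mix of cells. Single cells carried much of the cytokine RNA. Ccl1, a chemokine, was at 32.4 (17.4 to 68.0) in 7 against 3 cells, Il13 at least 46.3-fold higher in 1 cell, and Il2 at 7.91, or 1.80 without its top cell. In CD8 T-like cells activation genes had a median of 0.29 (Cd69 1.21, Tox 1.11, Cd28 1.14), and the histone deacetylase Hdac9 was at 2.22 (1.91 to 2.59). Filip1l (0.514) and Camk1d (0.617) were lower there, and both lead the mixed T cluster of the isotype library. Treg-like cells had S100a6, a calcium-binding gene, at 0.459 and the chemokine Cxcl10 at 3.37 (2.51 to 4.59). In follicular B-like cells immediate early and heat shock genes had a median of -0.25, with 14 of 15 lower (Junb 0.812, Hspa1b 0.535), glycolysis genes one of -0.11 (Gapdh 0.675, Eno1 0.712), and Socs3 was at 0.483 (0.437 to 0.533), the reverse of the glioma comparison, which shares the isotype library.

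**Figure D3:**
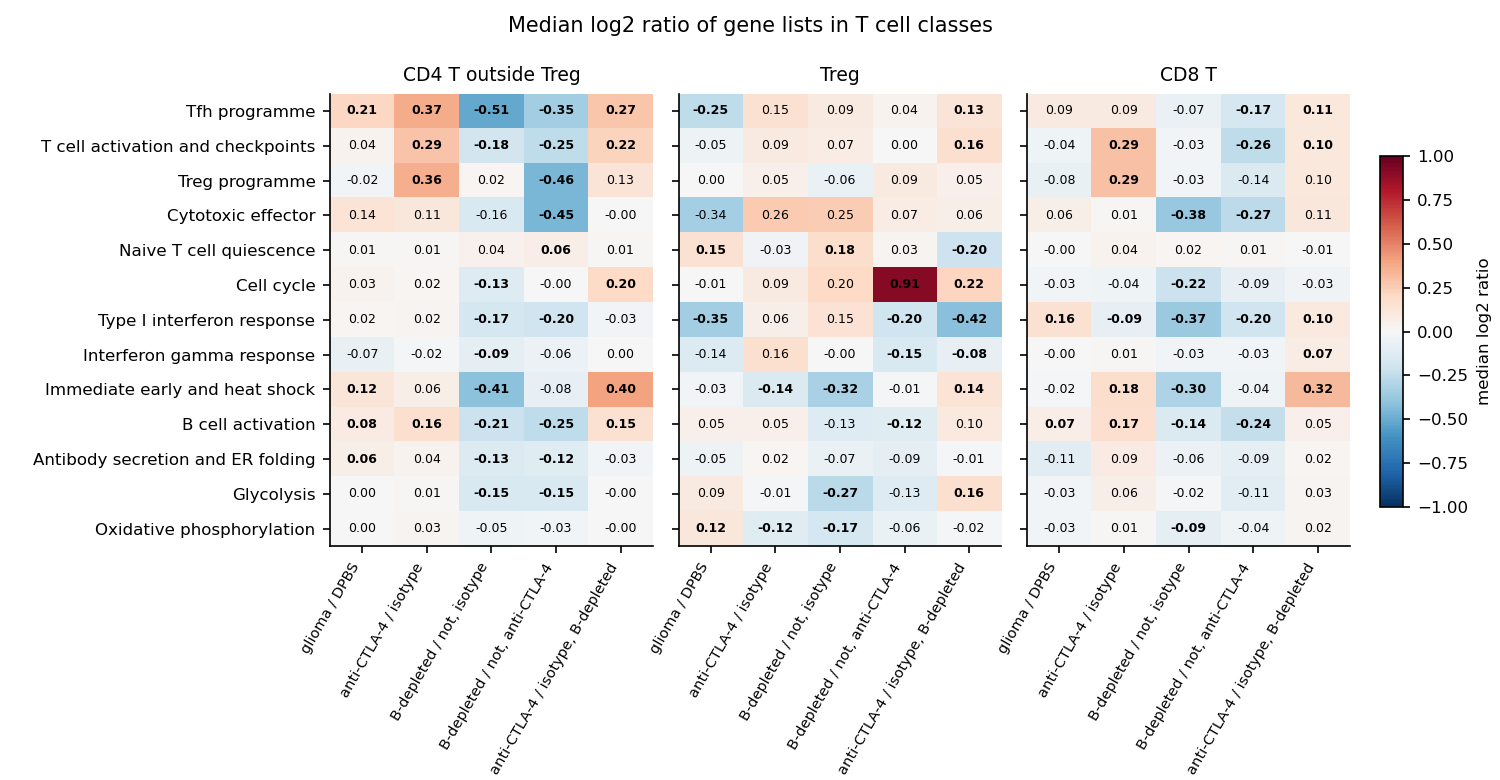
Median log2 ratio (colour and printed value) of gene lists (y axis) in 3 T cell classes (panels) and 5 comparisons (x axis), in bold where it fell outside the central 95% of random lists. The Tfh programme of conventional CD4 T cells was higher under anti-CTLA-4 (0.37) and lower after depletion (-0.51 under isotype, -0.35 under anti-CTLA-4), with the Tfh-like cells counted in that class.

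The next pair of comparisons asked how depletion of B cells altered the nodes, under isotype and under anti-CTLA-4. In both arms the B lineage was nearly gone, the few B cells left were rich in germinal centre B-like cells, and conventional CD4 T cells carried less RNA of several Tfh genes. Without the Tfh-like cells of that class this was smaller under anti-CTLA-4 and inside the range of random lists under isotype. Those cells were named on the genes of that list, so the setting does not tell a change within cells from one in their number. Tfh-like cells were fewer under anti-CTLA-4, while under isotype their share depended on the processing. The B lineage made up 0.831% (0.647 to 1.05) of cells in the depleted isotype and 1.16% (0.942 to 1.41) in the depleted anti-CTLA-4 library, 0.0159 (0.0126 to 0.0202) and 0.0238 (0.0195 to 0.0290) times the libraries with B cells. Germinal centre B-like cells were 22 of 69 B lineage cells (31.9%, 21.2 to 44.2) and 34 of 97 (35.1%, 25.6 to 45.4), ratios of 22.3 (14.6 to 33.9) and 11.6 (8.46 to 15.8), and the first was 45.7 with the gate on 3 marker genes. As shares of all cells they were lower, at 0.355 (0.219 to 0.575) and 0.274 (0.190 to 0.397) times. Follicular B-like cells were at 0.0102 (0.00755 to 0.0137) and 0.0140 (0.0107 to 0.0182) times. B cells fill much of the total only where they were not depleted. Set against cells outside the B lineage, both classes would therefore fall further than these ratios show. CD8 T-like cells made up 40.5% and 41.6% of all cells, against 19.8% and 21.2% with B cells, while their share of T cells was close (41.9% and 43.3% against 42.8% and 42.9%).

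Tfh-like cells made up 0.263% of CD4 T cells in the depleted isotype library and 0.460% in the depleted anti-CTLA-4 library, 0.335 (0.154 to 0.728) and 0.269 (0.158 to 0.458) times the libraries with B cells. The first ratio was not stable, at 0.831 with the kept-out cluster, 0.892 with a marker gate and 1.52 with no doublet removal, and the second was 0.755 with the marker gate. Treg-like cells were at 0.809 (0.724 to 0.905) and 0.886 (0.805 to 0.9747) times. Effector T-like cells made up 5.83% of T cells in the depleted isotype library, 0.705 (0.616 to 0.806) times the share with B cells, and the ratio under anti-CTLA-4 was 0.913 (0.808 to 1.03).

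Under isotype, depletion left the Tfh programme of conventional CD4 T cells at a median log2 ratio of -0.51, with 9 of 12 genes lower, or -0.10 without the Tfh-like cells. Its members with most UMIs were among the exceptions or close to level (Izumo1r 0.930, Slamf6 1.22, Sh2d1a 1.15, Icos 1.24). Pdcd1 was at 0.399, Il21, the cytokine that drives germinal centre B cells, at 0.357 and the follicle-homing receptor Cxcr5 at 0.672, all 3 chosen after their values were seen. Without the Tfh-like cells Pdcd1 was at 0.557 (0.419 to 0.742), while Il21 (0.455 to 2.31) and Cxcr5 (0.658 to 1.29) had intervals that hold 1. B cell activation genes, many of them targets of NF-kB in T cells too, had a median of -0.21, with 13 of 14 lower (Ccr7 0.969, Nfkbia 0.891). Immediate early and heat shock genes had one of -0.41 (Junb 0.747, Hspa1b 0.553, Hspa1a 0.529). The base of this comparison is the isotype library with the lowest mitochondrial share, so its handling and depletion cannot be separated here. CD8 T-like cells had a median of -0.37 in the type I interferon list, with 14 of 15 lower (Irf7 0.787, Isg15 0.663, Ifit3 0.583), and one of -0.38 in the cytotoxic effector list (Ccl5 0.607, Nkg7 0.9746, Cxcr3 0.894), which was -0.19 among members with at least 100 UMIs. Treg-like cells were lower in glycolysis (-0.27, Gapdh 0.837, Ldha 0.821) and in oxidative phosphorylation (-0.17, all 11 lower), and higher in naive T cell quiescence (0.18, Satb1 1.17, although Klf2 was at 0.588). Among single genes Sostdc1 was at 0.0647 (0.0414 to 0.0974) and Penk at 0.218 in conventional CD4 T cells, the growth factor Areg at 0.384 in Treg-like cells, or 0.502 without its top cells, and Farp2 at 2.54 in CD8 T-like cells. The MHC class II presentation list was lower in all 3 T cell classes, with medians of -1.004 in conventional CD4, -1.08 in Treg-like and -2.49 in CD8 T-like cells (Cd74 0.371, 0.474 and 0.130), or -0.75, -0.27 and -1.54 among members with at least 100 UMIs, and the constant genes other than IgG were at -2.02 in conventional CD4 T cells. In CD8 T-like cells of the isotype library with B cells Cd74 lay under 1% of its follicular B-like level. So did the median of the B cell markers (0.382%), although Cd79b lay at 1.65% and Ighd at 1.40%. H2-DMa, chosen after its values were seen, lay at 10.8% there and was level after depletion (0.978).

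Under anti-CTLA-4, depletion left all 12 Tfh programme genes of conventional CD4 T cells lower, with a median of -0.35 (Izumo1r 0.841, Sh2d1a 0.839, Slamf6 0.957, Icos 0.892), or -0.18 without the Tfh-like cells. Pdcd1 was at 0.484, Tox2 at 0.480, Cxcr5 at 0.635 and Maf at 0.598, all 4 chosen after their values were seen. Without the Tfh-like cells Tox2 (0.676, 0.512 to 0.896) and Maf (0.753, 0.621 to 0.915) stayed lower. The intervals of Pdcd1 (0.688 to 1.12) and Cxcr5 (0.699 to 1.23) then hold 1. The kept-out cluster, at 0.535 (0.309 to 0.926) times its share with B cells, was still counted in this setting. Activation and checkpoint genes had a median of -0.25, with 12 of 13 lower (Tox 0.994, Cd28 0.922, Cd69 0.839), the Treg programme one of -0.46 (Ctla4 0.863, Tnfrsf4 0.782, Ikzf2 0.669), or -0.21 without the Tfh-like cells, and cytotoxic effector genes one of -0.45 (Nkg7 0.714, Ifng 0.587). Igfbp4, a marker of naive cells, was at 1.49 (1.46 to 1.54). CD8 T-like cells were lower in activation (-0.26, Cd69 0.804, Cd28 0.837) and in the cytotoxic list (-0.27, Ccl5 0.826), and Hdac9 was at 0.302. In Treg-like cells the cell cycle list had a median of 0.91, or 0.35 among members with at least 100 UMIs (Pcna 1.39), and the proliferation marker Mki67 was at 4.05 (2.85 to 5.92), in 53 against 13 cells. The MHC class II presentation list again had low medians in the 3 T cell classes, but in Treg-like cells that of -1.02 was -0.15 among members with at least 100 UMIs, inside the range of random lists. In conventional CD4 T cells its median was -1.48, or -0.93 among members with at least 100 UMIs. The 55 follicular B-like cells left had a median of 3.00 in the germinal centre programme (Bcl6 0.649, Eaf2 2.49, Mef2b 2.74, Basp1 9.70), or 1.52 among members with at least 100 UMIs, and Jchain, the joining chain of secreted IgM and IgA, was at 130 (83.2 to 208), in 10 against 28 cells. A UMI of a T cell gene was held by 16 of these 55 cells (29.1%), against 5.84% with B cells present, so droplets with T cell RNA may be among them, and without such cells the median was 1.83 and Jchain was at 36.5 (16.6 to 75.9). A cluster led by Fcrl5 and holding Plac8 among its leading genes made up 32.7% of these cells and 1.78% of those with B cells present, so values within the class compare different mixtures.

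The last comparison asked whether anti-CTLA-4 acted alike where B cells had been depleted. The Tfh programme and activation genes were higher in conventional CD4 T cells under anti-CTLA-4 here too, by smaller medians, while Tfh-like cells made up 0.460% against 0.263% of CD4 T cells, with a ratio of 1.75 (0.833 to 3.67) that holds 1 and was 1.06 with the kept-out cluster and 0.9195 with no doublet removal. The Tfh programme had a median of 0.27, with 10 of 12 higher, although the members with most UMIs were close to level (Izumo1r 1.10, Slamf6 0.973, Icos 0.994), and without the Tfh-like cells the median was 0.12. Il4, a helper cytokine that leads the Tfh-like cluster, was at 10.5 (5.46 to 22.5), in 12 against 5 cells, or 1.47 without the Tfh-like cells, Asb2 at 3.79 (2.37 to 6.30), or 2.06, and the growth factor Il2 at 2.82 (2.14 to 3.75). Activation genes had a median of 0.22 in conventional CD4 T cells (Cd69 1.17) and 0.16 in Treg-like cells (Tnfrsf4 1.17). Immediate early and heat shock genes were all higher in conventional CD4 (0.40, Junb 1.23, Hspa1b 1.46) and CD8 T-like cells (0.32, Junb 1.17, Hspa1a 1.51). Treg-like cells were lower in the type I interferon list (-0.42, Ifi27l2a 0.779, Isg15 0.7498), which was -0.26 among members with at least 100 UMIs, and in quiescence genes (-0.20, Klf2 0.851, Satb1 0.824), and higher in the cell cycle list (0.22, Pcna 1.34), which was 0.16 and inside the range of random lists among members with at least 100 UMIs. Klrg1, a receptor of differentiated cells, was at 0.426, or 0.611 without its top cells, and Dusp14, a phosphatase, at 2.55 in Treg-like cells. The Treg-like share of CD4 T cells was 1.15 (1.05 to 1.26) times and the effector T-like share of T cells 1.22 (1.08 to 1.37) times the depleted isotype share.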

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

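Of the tests named here, those on cells without mitochondrial UMIs, on cell classes, on B cell markers in T cells, on the largest clone and on Ighg1 in follicular B-like and CD8 T-like cells were chosen after the result was seen.

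In 3 results anti-CTLA-4 over isotype went one way in mice with B cells and the other way after depletion, and in each the difference was not tested. Counted were shares whose intervals lay on opposite sides of 1 and list medians outside the central 95% of random lists on opposite sides of 0, so shares with 1 interval that holds 1 are left out. The B lineage share of all cells had a ratio of 0.937 with B cells and 1.40 after depletion, where it rests on 69 and 97 cells. The median log2 ratio of immediate early and heat shock genes in Treg-like cells was -0.14 with B cells and 0.14 after depletion. That of type I interferon response genes in CD8 T-like cells was -0.085 with B cells and 0.10 after depletion, where it was 0.0728 and inside the range of random lists among members with at least 100 UMIs.

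The isotype glioma library had the lowest mitochondrial share, with all 13 mitochondrial genes below each of the other libraries. A subset of cells with almost no mitochondrial UMIs may add to this but is not the whole cause, since without cells under 0.5% the library's median was 0.609 times the lowest of the others. In the 5 classes tested the ratio was at most 0.609 (conventional CD4 T cells, here without the Tfh-like cells). In germinal centre B-like cells it was 0.644, so a different mix of these classes is not the whole cause. Among cells of 3000 to 6000 UMIs it was 0.567, so neither is depth per cell. Handling of this 1 library and the treatment cannot be separated, since isotype glioma mice with B cells have no other library. The library enters 3 of the 5 comparisons.

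T cells of the depleted libraries had fewer MHC class II UMIs. Free RNA from B cells is a candidate explanation, since in CD8 T-like cells the median log2 ratio of 8 B cell markers was -3.32 after depletion under isotype, below the -1.45 of all MHC class II genes and the -2.49 of those with at least 20 UMIs. RNA made by the T cells themselves stays open, since the median of the list, at most 0.827 times the share of the B cell level that the B cell markers reached in CD8 T-like cells, hides H2-DMa at 10.8% to 11.52% and Ctss at 26.8% to 28.7% of that level. The median alone was first taken to exclude this, and the members were looked at, and the reading changed, after that result was seen. H2-DMa was level in CD8 T-like cells after depletion under isotype, so its own level does not account for the fall there. Cd74, which fell, lay at 0.242% of its B cell level in CD8 T-like cells of the isotype library. The median of the B cell markers there was 0.382%. A Cd74 UMI was seen in 38.2% and 45.8% of Treg-like cells under isotype and anti-CTLA-4 with B cells and in 31.8% and 31.3% after depletion, against 20.6% and 27.2%, then 3.90% and 3.45%, of CD8 T-like cells, and when thinned to 1000 UMIs in 11.3% and 15.8%, then 9.32% and 10.5%, of Treg-like cells.

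More germinal centre B-like cells carried IgG1 under anti-CTLA-4. A single expanded clone is argued against for the IgG1 share of all cells with a heavy chain. Without the largest IgG1 clone of each library the ratio of these shares was 3.19 with a lower bound of 1.90. The test did not single out germinal centre B-like cells, so it does not settle the matter within that class. There the largest anti-CTLA-4 clone held 13 of the 60 IgG1 cells. Free IgG1 RNA would also reach other cells, yet in the expression library of anti-CTLA-4 Ighg1 stood at 565 CPM in germinal centre B-like, 1.34 in follicular B-like and 0.249 in CD8 T-like cells, so that the higher of the others was 0.237% of the first. The constant gene calls matched the expression library, where Ighg1 stood 19.5 times higher in 60 germinal centre B-like cells with an IgG1 receptor (1183 CPM) than in 40 with an IgM receptor (60.8). A response to the antibody is consistent with these values, as is a difference between the mice of 2 libraries.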

How the results depend on the processing

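No paired analysis was possible because each group had 1 library. A value counted as reversed only where its main interval excluded no change (for a list, its median lay outside the range of random lists) and the alternative lay on the other side of it, so a ratio whose main interval held 1 could cross 1 and count as stayed or moved. Of 1324 list medians under the alternatives 1289 stayed within their spread, 31 moved and 4 reversed; of 628 named-gene ratios 593 stayed, 33 moved and 2 reversed; of 579 ratios of shares 539 stayed, 37 moved and 3 reversed; of 684 shares per library 570 stayed and 114 moved. Leaving out cells under 0.5% mitochondrial UMIs, leaving out top cells, leaving Tfh-like cells out of the conventional CD4 T cells, leaving out B cells with a UMI of a T cell gene, counting the kept-out cluster and splitting mutated shares by antibody class were chosen after seeing the data. The cause was not tested for any value that follows.

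With at least 5 mismatches the glioma ratio of mutated shares was 0.449 for all cells, 0.168 for IgM and IgD, 0.140 for IgG and 0.0833 for IgG1 cells, and the anti-CTLA-4 ratio 5.68 for IgG1 and 8.47 for IgM and IgD cells, where the IgG1 and the IgM and IgD values rest on 1 isotype cell. At Leiden resolution 2 the CD8 T-like share of all cells reversed to 0.932 for anti-CTLA-4 and to 1.04 for glioma, and was 1.77 for depletion under isotype. With at least 200 genes and at most 20% mitochondrial UMIs it was 1.01 for anti-CTLA-4 and 1.93 for depletion under isotype, and the B lineage ratio for depletion under anti-CTLA-4 was 0.0298. With no doublet removal it was 1.01 for anti-CTLA-4 and 2.14 for depletion under anti-CTLA-4, and the Tfh-like ratio was 0.545 for glioma, 5.25 for anti-CTLA-4 and, reversed, 1.52 for depletion under isotype. Marker gates gave Tfh-like ratios of 0.892 and 0.755 for depletion under isotype and anti-CTLA-4, and germinal centre B-like ratios of 1.16 for glioma, 5.28 for anti-CTLA-4 and 45.7 for depletion under isotype. With the kept-out cluster the Tfh-like ratio for depletion under isotype was 0.831. At 85% CDR3 identity the clone share ratio for anti-CTLA-4 was 1.06 and distinct clones were 95.6%, 95.4% and 95.4% of cells in the saline control, isotype and anti-CTLA-4 libraries; with the clonotype of the authors' software they were 98.8% in the last.

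Among list members with at least 100 UMIs, MHC class II presentation medians were -0.75 in conventional CD4, -0.27 in Treg-like and -1.54 in CD8 T-like cells for depletion under isotype, and -0.93, -0.15 and -1.83 under anti-CTLA-4. The cytotoxic median was -0.19 in CD8 T-like cells for depletion under isotype, type I interferon -0.23 in follicular B-like cells for glioma and -0.26 in Treg-like cells for anti-CTLA-4 after depletion, and Tfh 0.070 in conventional CD4 T cells for glioma. Cell cycle was 0.40 in follicular B-like cells for glioma, 0.35 in Treg-like cells for depletion under anti-CTLA-4 and 0.074 in conventional CD4 T cells for anti-CTLA-4 after depletion. The germinal centre programme in follicular B-like cells for depletion under anti-CTLA-4 was 1.52, and 2.36 without cells under 0.5% mitochondrial UMIs. Without Tfh-like cells the Tfh median of conventional CD4 T cells reversed to -0.092 for glioma and was -0.10 and -0.18 for depletion under isotype and anti-CTLA-4 and 0.12 for anti-CTLA-4 after depletion, activation and checkpoints reversed to 0.075 for depletion under isotype, and the Treg programme was -0.21 for depletion under anti-CTLA-4. Without B cells with a UMI of a T cell gene the median in follicular B-like cells was 0.60 for cell cycle and, reversed, -0.24 for cytotoxic genes with glioma, and 1.83 for the germinal centre and 2.11 for the Treg programme in depletion under anti-CTLA-4, and antibody secretion in germinal centre B-like cells reversed to 0.18 for anti-CTLA-4. Without the top cells, Spp1 in conventional CD4 T cells reversed to 1.15 for glioma and Il2 to 1.21 for depletion under anti-CTLA-4. No ILC-like cluster formed in 3 of the 5 other clusterings, so its share had no value there. Depth limits plasma cell-like and Tfh-like shares, which rest on 6 to 46 cells per library with B cells.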

Other observations

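The test on Ms4a1 in germinal centre B-like cells was chosen after the result was seen, and so were the shares outside the B lineage given here.

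Among cells outside the B lineage, the nodes of depleted mice held smaller shares of plasmacytoid dendritic-like (pDC) and innate lymphoid-like (ILC) cells in both treatment arms, the latter a class for which no cluster formed in 3 of the 5 other clusterings. The pDC-like share of cells outside the B lineage was 0.708% under isotype and 0.572% under anti-CTLA-4 with B cells, and 0.328% and 0.254% after depletion, ratios of 0.463 (0.276 to 0.778) and 0.444 (0.256 to 0.773). The ILC-like share was 0.519% and 0.443% with B cells and 0.182% and 0.181% after depletion, ratios of 0.351 (0.182 to 0.676) and 0.410 (0.215 to 0.781). As a share of all cells the pDC-like ratios were close to level, at 0.959 (0.571 to 1.61) and 0.858 (0.494 to 1.49), since B cells then count in the total. Both classes rest on 15 to 31 cells per library. NK-like cells were at 0.632 (0.446 to 0.895) under isotype and 0.856 under anti-CTLA-4, and migratory dendritic-like cells were close to level (1.11 and 1.09). Gamma-delta T-like cells made up 1.37% and 0.940% with B cells and 0.947% and 0.823% after depletion. Monocyte or macrophage-like cells made up 0.803% and 0.590%, then 0.753% and 0.423%. Lower shares were thus not particular to pDC-like and ILC-like cells.

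Most plasma cell-like cells were switched, and few were mutated. In the isotype glioma library 24 of 36 had an IgG receptor, 7 an IgM receptor, and 3 of 35 were mutated (8.57%), and under anti-CTLA-4 16 of 21 had an IgG receptor, 4 an IgM receptor, and 2 of 21 were mutated (9.52%). Of these plasma cell-like cells 24 of 36 and 11 of 21 were in clones, so the counts rest on fewer independent cells. Germinal centre B-like cells were mutated in 13 of 16 cases (81.2%) in the saline control, 17 of 43 (39.5%) under isotype and 70 of 107 (65.4%) under anti-CTLA-4, so the isotype share was the lowest of the 3, with ratios of 0.487 (0.314 to 0.754) over saline and 1.65 (1.12 to 2.46) for anti-CTLA-4 over isotype. These intervals count each cell as independent, although 6 of 16, 11 of 43 and 38 of 109 germinal centre B-like cells were in clones. They may therefore be too narrow. The clones also differed. The largest clone under isotype had 10 cells, all plasma cell-like, with 5 IgM and 5 IgG2c receptors on IGHV1-72, while the largest under anti-CTLA-4 had 14 cells, all IgG1 on IGHV9-3, of which 13 were germinal centre B-like. In the saline control the largest clone had 6 cells, all IgA, of which 1 was germinal centre B-like and 2 plasma cell-like. Of the 12 IgA cells of that library 4 were matched to classes outside the B lineage. Its largest clone had 4 cells where the light chain had to match too, and 3 with the clonotype of the authors' software. The isotype and anti-CTLA-4 libraries shared 1 clone, and the isotype and saline control libraries 5.

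Among the B cells left after anti-CD20, 31.9% and 35.1% were germinal centre B-like. Less CD20 RNA in these cells might have spared them, but Ms4a1 CPM were at least 1.38 times higher in germinal centre B-like than in follicular B-like cells in each of the 3 libraries with B cells. That argues against lower Ms4a1 RNA as the reason, and CD20 protein was not measured. The follicular B-like cells left held a cluster led by Fcrl5 at 32.6% and 32.7% in the depleted isotype and anti-CTLA-4 libraries, against 1.15% and 1.78% with B cells.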
